A study of Ovis aries with 8 samples.

How the data were processed

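RNA was measured in the duodenum of 8 sheep aged 1 year, 4 from a high-diarrhoea group and 4 from a low-diarrhoea group, which the series names as the control. Total RNA was extracted with a column kit that included a DNase step and sequenced on the DNBSeq platform, per the labels' protocols. The submitters' processing notes name STAR 2.7.3a, featureCounts, Subread 2.0.0 and DESeq2, without a role or an order for each. The genome build, the annotation and the strand setting were not given in the sources used here.

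The authors deposited raw read counts per gene for the 8 libraries, with 33624 gene identifiers. They also deposited a table whose normalised signal values equal those counts divided by 1 factor per library, and this was checked for every count above 0. Per the file headers, that table further holds the authors' log2 fold change with its standard error, the test score (Wald statistic), the p-value and the adjusted p-value of high against low diarrhoea. Of the identifiers, 26312 were found in the RefSeq gene table of the assembly ARS-UI_Ramb_v3.0, which was used only for names, gene types and which genes overlap. There were 15528 numbered LOC identifiers, and 412 of them received the symbol that this table gives the same gene number.

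Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr given the groups, which left 16159, and libraries were scaled by TMM. The main test was edgeR's two-sided quasi-likelihood test of high over low diarrhoea with group as the only term, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each standard error is the one implied by the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Gene lists were tested on log2 CPM with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 33 lists with at least 3 tested members. Camera with an estimated correlation, fry, and an exact permutation test of each list's score (the mean z of log2 CPM over its members) were run beside it. With 4 against 4 libraries there are 70 assignments, so an exact two-sided p cannot go below 0.0286.

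The groups, the tests, the 36 lists and the rule for naming genes were fixed before the data were examined. Because no gene passed, the rule named the 5 lowest unadjusted p in each direction, up to 4 members with the lowest p in the direction of each list past the camera threshold, and a fixed set of immune, mucus and transport genes. The text gives all 4 for smooth muscle and at most the first 2 for the other lists, and some genes that the rule named are not reported here. Copies of a gene, immunoglobulin segments and major histocompatibility genes share reads and are uncertain. So are genes that overlap another gene, since the strand setting is not known.

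The test was checked on simulated counts for this comparison, with 100 genes changed 2-fold and 100 changed 4-fold among 16159. With each gene's own dispersion edgeR recovered 23% of the 2-fold and 84% of the 4-fold changes with 3 false calls, and DESeq2 1.42.0 recovered 59% and 91% with 55 false calls. The alternatives chosen at the outset were DESeq2, limma-voom with and without sample quality weights, limma on log2 of the authors' normalised values plus 1, other scaling factors, other low-count filters, a robust fit, a replicate block, other thresholds and leaving out each library. Alternatives added after seeing the data were a smooth muscle covariate, edgeR's likelihood-ratio test, DESeq2 on all genes, DESeq2 without the high diarrhoea 1 library, lists without shared members and camera with an estimated correlation without that library. An exact test in edgeR was also looked at during exploration and is not reported. The closest pair of libraries, low diarrhoea 1 and 2, differed far beyond counting noise (chi-square per degree of freedom 29.4), so all 8 were treated as separate samples.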

Results

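Duodenal RNA was sequenced from 8 sheep aged 1 year, 4 with high and 4 with low diarrhoea, described by the series as biological replicates. Each library held between 19011561 and 22231223 counted reads. The mean total was 21320000 ± 924200 (SD, n = 4) in high and 19810000 ± 831800 (SD, n = 4) in low diarrhoea (exact permutation p = 0.0857, adjusted p = 0.107 over 10 library measures), and between 19887 and 20858 genes had at least 1 read. The series asks whether an over-reactive duodenal response to parasitic worms goes with susceptibility to diarrhoea in Merino sheep. The comparison of high with low diarrhoea addresses this for gene expression.

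In high diarrhoea, genes of smooth muscle and connective tissue and the mitochondrially encoded genes ranked higher than other genes. Genes of macrophages and dendritic cells, T cells, cytotoxic cells, antigen presentation, plasma cells and absorptive enterocytes ranked lower. The type 2 response and mast cell lists did not differ past the threshold, but only 16 of 27 and 8 of 22 listed genes were tested. IL4, IL5, IL13 and CPA3, classical genes of immunity to worms, were not among them. The eosinophil list, with 6 of 16 listed genes tested, ranked lower. In camera with the preset correlation, 20 of 33 lists passed, 5 higher and 15 lower. With an estimated correlation 0 did (2 at an unadjusted p below 0.05). Camera with the preset correlation also passed 4 to 23 lists in every other split of the 8 libraries into 4 and 4. Passing it therefore says little by itself about the diarrhoea groups. No single gene passed in edgeR's quasi-likelihood test.

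That test called 0 of 16159 genes, with 2645 at an unadjusted p below 0.05 (1839 higher, 806 lower) and a lowest adjusted p of 0.189. Limma-voom also called 0, with 2492 at an unadjusted p below 0.05, whereas DESeq2 called 798, of which 629 were higher and 169 lower. Without high diarrhoea 1 DESeq2 called 259, of which 155 were higher and 104 lower. The groups did not overlap in log2 CPM for 1243 genes, 7.69% of those tested, where chance gives 2.86% on average. Genes vary together, so this share can differ widely between splits, and its spread over splits was not computed. Over lists, camera with an estimated correlation called 0 (2 at an unadjusted p below 0.05), fry 0 (10) and the exact permutation test of list scores 0 (6). No list member passed over all genes tested, so counts of members below are those adjusted over the list alone.

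**Figure D1:**
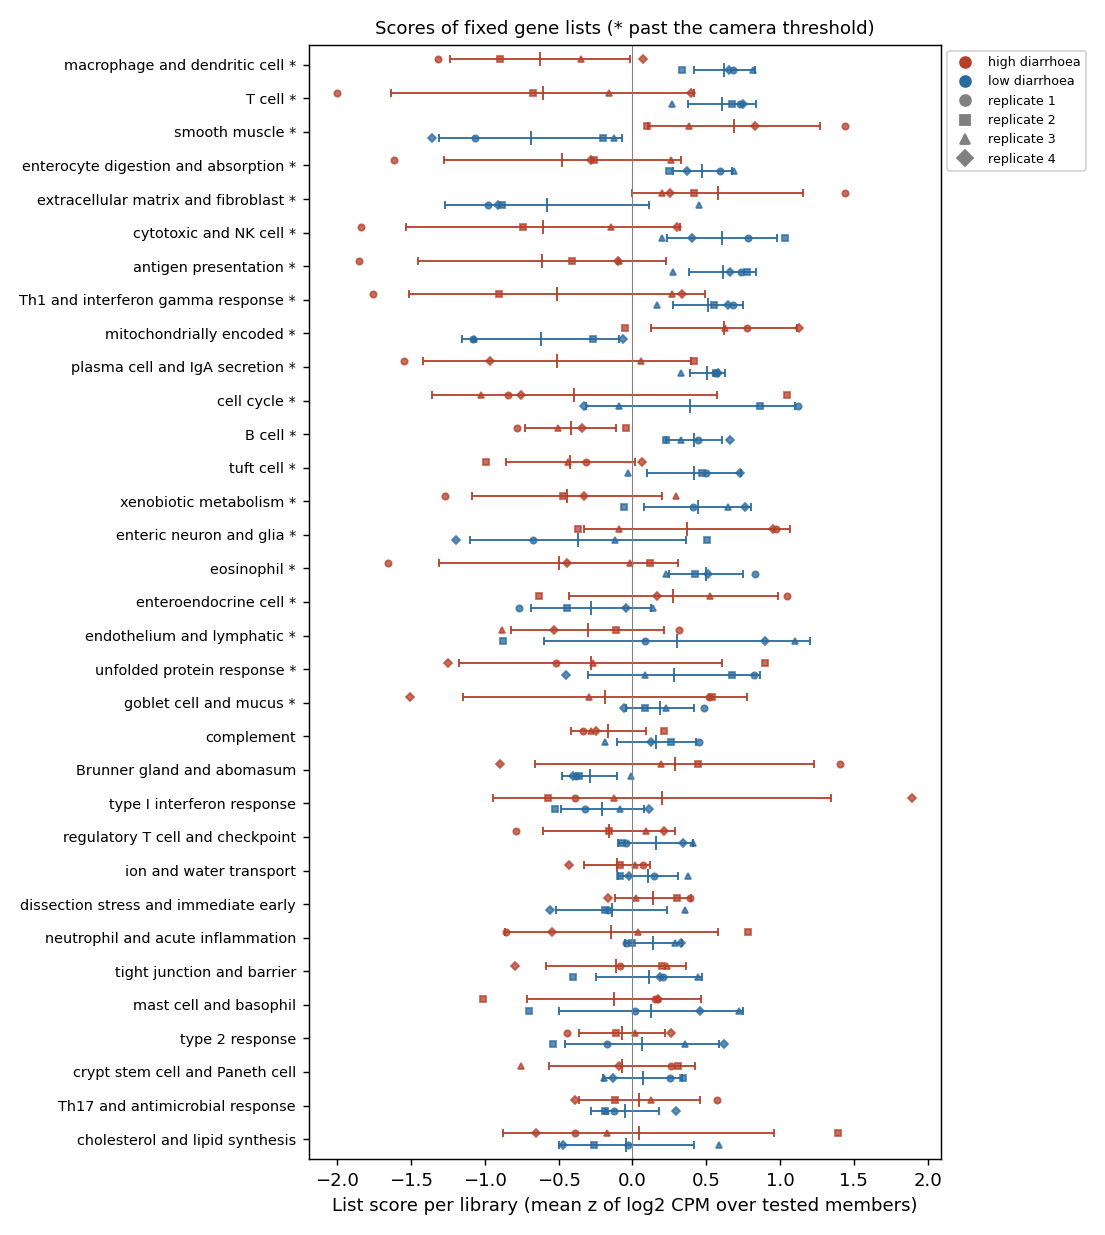
Score of each tested gene list in each library (horizontal axis, mean z of log2 CPM over tested members, no unit), with the group mean and SD bars (n = 4 per group) and marker shapes for replicate numbers. All 4 high-diarrhoea libraries lie above all 4 low-diarrhoea libraries for smooth muscle and for the mitochondrially encoded genes, and below them for macrophage and dendritic cell, antigen presentation, B cell and eosinophil.

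Smooth muscle genes had the largest difference among the lists that passed. All 13 tested members were higher in high diarrhoea, 12 of them past the threshold adjusted over the list alone, with a median log2 fold change of 2.29 (camera adjusted p = 8.44e-09). With an estimated correlation the list did not pass (adjusted p = 0.371 with an estimated correlation). SYNM, an intermediate filament protein, had a log2 fold change of 2.85 ± 0.68 (SE), SYNPO2, an actin-binding protein, 2.80 ± 0.69 and CALD1, an actin-binding regulator of contraction, 2.66 ± 0.67. MYH11, the smooth muscle myosin heavy chain, measured 2730 CPM ± 2459 (SD, n = 4) in high and 413 CPM ± 292 (SD, n = 4) in low diarrhoea. The score was 1.44 in high diarrhoea 1 and between 0.0979 and 0.827 in the other high-diarrhoea libraries, against -1.36 to -0.122 in low diarrhoea. Without high diarrhoea 1 the camera adjusted p was 8.2e-09, the log2 fold change of CALD1 1.77 and the mean of MYH11 in high diarrhoea 1520 CPM.

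Extracellular matrix and fibroblast genes were higher in all 21 tested members, 10 of them past the threshold adjusted over the list alone, with a median log2 fold change of 0.88 (camera adjusted p = 3.92e-08; adjusted p = 0.371 with an estimated correlation). The group scores overlapped (exact permutation p = 0.114), with low diarrhoea 3 (0.454) above high diarrhoea 2, 3 and 4 (0.419, 0.202 and 0.258). FN1, which encodes fibronectin, had 2.42 ± 0.60 (SE) and the collagen gene COL6A3 1.14 ± 0.33. Enteric neuron and glia genes were higher in 15 of 16 members, 0 adjusted over the list alone in edgeR (3 at an unadjusted p below 0.05, 1 called by DESeq2), with a median of 0.74 (camera adjusted p = 0.00372; adjusted p = 0.572 with an estimated correlation). SNAP25, a synaptic vesicle fusion protein, had 1.66 ± 0.48 and the glial calcium-binding protein S100B 0.80 ± 0.33. Without low diarrhoea 4 the neuron and glia list no longer passed (camera adjusted p = 0.117). High diarrhoea 1, the highest in the smooth muscle score, was also the highest in both lists (1.44 and 0.974). Without it the median was 0.566 for matrix and 0.461 for neuron and glia genes, and the log2 fold change was 1.6 for FN1 and 0.469 for S100B.

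Of the 13 mitochondrially encoded genes, 12 were higher, 4 past the threshold adjusted over the list alone, with a median log2 fold change of 0.53 (camera adjusted p = 3.32e-06; adjusted p = 0.371 with an estimated correlation). The complex I subunit genes ND5 and ND2 had 0.89 ± 0.19 (SE) and 0.61 ± 0.19. These genes took 7.53% ± 0.926 (SD, n = 4) of reads in high and 5.43% ± 0.700 (SD, n = 4) in low diarrhoea (exact permutation p = 0.0286, the smallest this design gives; adjusted p = 0.0952 over the 10 library measures).

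Macrophage and dendritic cell genes were lower in all 21 tested members, 5 of them past the threshold adjusted over the list alone, with a median log2 fold change of -0.65 (camera adjusted p = 8.64e-10; adjusted p = 0.371 with an estimated correlation). ITGAX, the integrin CD11c of dendritic cells, measured 3.82 CPM ± 0.862 (SD, n = 4) in high and 8.75 CPM ± 1.66 (SD, n = 4) in low diarrhoea, and the lysosomal macrophage marker CD68 had a log2 fold change of -0.83 ± 0.20 (SE). Antigen presentation genes were lower in all 14 members, 1 adjusted over the list alone, with a median of -0.68 (camera adjusted p = 4.2e-07; adjusted p = 0.371 with an estimated correlation). The class II chain gene DQA had -1.27 ± 0.32, which is uncertain because histocompatibility genes share reads, and CD74, the invariant chain that accompanies class II, had -1.09 ± 0.34. Th1 and interferon gamma response genes were lower in 17 of 18 members, 0 adjusted over the list alone in edgeR (7 at an unadjusted p below 0.05, 0 called by DESeq2), with a median of -0.64 (camera adjusted p = 2.12e-06; adjusted p = 0.371 with an estimated correlation). CIITA, the class II transactivator, had -0.81 ± 0.26 and the interferon-inducible tRNA synthetase WARS -1.08 ± 0.40. IFNG itself had -0.58 ± 0.58, and without high diarrhoea 1, 3 or 4 or low diarrhoea 1 it had -0.212, -0.895, -0.958 or -0.386. Without high diarrhoea 1 the median of the Th1 list was -0.414.

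T cell genes were lower in all 19 members, 2 past the threshold adjusted over the list alone, with a median log2 fold change of -0.82 (camera adjusted p = 8.44e-09; adjusted p = 0.371 with an estimated correlation). The T cell surface receptors CD5 and CD6 had -0.94 ± 0.24 (SE) and -1.09 ± 0.29. Cytotoxic and NK cell genes were lower in all 14 members, 3 adjusted over the list alone, with a median of -0.92 (camera adjusted p = 1.9e-07; adjusted p = 0.371 with an estimated correlation). GNLY, the cytolytic granule protein granulysin, had -1.44 ± 0.36 and granzyme A (GZMA) -1.09 ± 0.30. The library with the highest smooth muscle score, high diarrhoea 1, also had the lowest T cell score (-1.997), cytotoxic score (-1.84) and macrophage and dendritic cell score (-1.32). Without it the camera adjusted p was 1.61e-09 for T cells, 5.85e-08 for cytotoxic cells and 5.12e-11 for macrophages and dendritic cells, and the median of the cytotoxic list was -0.615. With an estimated correlation, however, 0 lists passed in camera without this library. The group scores overlapped for T cells, with high diarrhoea 4 (0.4005) above low diarrhoea 3 (0.2657). They also overlapped for cytotoxic cells (0.3016 against 0.1996 in the same libraries). The exact permutation p was 0.0571 for each of these lists.

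B cell genes were lower in 14 of 18 members, 0 adjusted over the list alone in edgeR (6 at an unadjusted p below 0.05, 3 called by DESeq2), with a median log2 fold change of -0.46 (camera adjusted p = 9.83e-05; adjusted p = 0.371 with an estimated correlation). The B cell transcription factor SPIB had -0.95 ± 0.24 (SE) and TNFRSF13C, the receptor of the survival factor BAFF, -0.91 ± 0.27. Plasma cell and IgA secretion genes were lower in 14 of 15 members, 4 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 1.33e-05; adjusted p = 0.371 with an estimated correlation). TNFRSF17, the plasma cell receptor BCMA, had -0.89 ± 0.26 and TXNDC5, a disulfide isomerase of the secretory pathway, -0.78 ± 0.24. Without high diarrhoea 1 the median of the plasma cell list was -0.311. The most abundant constant-region segment, LOC101107475, took 1.31% ± 0.707 (SD, n = 4) of reads in high and 2.72% ± 0.146 (SD, n = 4) in low diarrhoea (exact permutation p = 0.0286, adjusted p = 0.0952). JCHAIN, the joining chain of secreted IgA, was listed at 0 in every library and says nothing here.

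**Figure D2:**
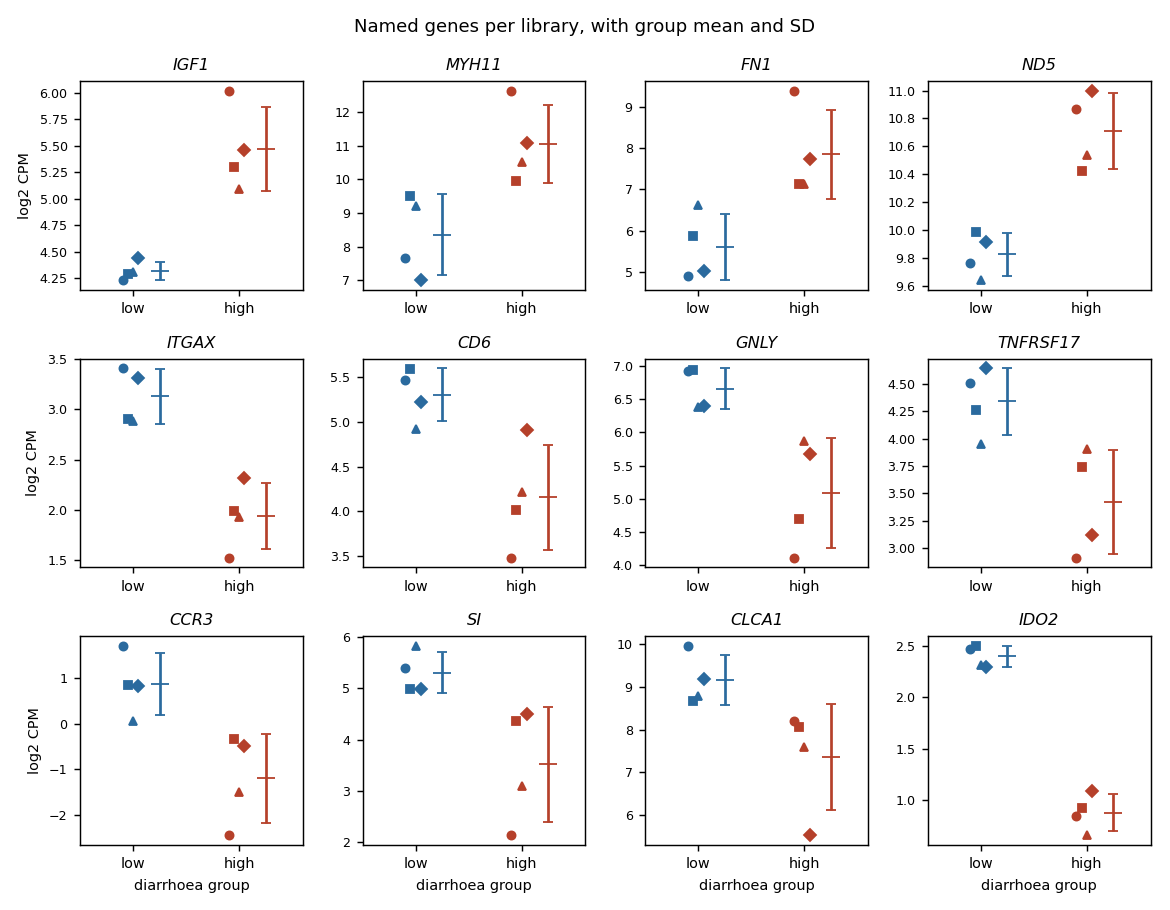
Log2 CPM of 12 named genes in each library (vertical axes, each with its own range), by diarrhoea group, with the mean and SD beside the points (n = 4 per group) and marker shapes for replicate numbers as in the plot of list scores. The 12 were picked for the plot after the values were seen, and the groups do not overlap for any of them, for example CD6 at 3.48 to 4.91 in high and 4.92 to 5.60 in low diarrhoea.

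Enterocyte digestion and absorption genes were lower in 31 of 33 members, 0 adjusted over the list alone in edgeR (9 at an unadjusted p below 0.05, 3 called by DESeq2), with a median log2 fold change of -0.73 (camera adjusted p = 2.05e-08; adjusted p = 0.371 with an estimated correlation). The glucose transporter gene SLC2A2 had -1.80 ± 0.53 (SE) and SI, the brush border enzyme sucrase-isomaltase, -1.54 ± 0.47. SLC2A2 was low in both groups, at 0.69 CPM in high and 2.42 CPM in low diarrhoea. Xenobiotic metabolism genes were lower in 12 of 13 members, 1 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 0.000583; adjusted p = 0.371 with an estimated correlation). The carboxylesterase CES2 had -1.01 ± 0.23 and NR1I2, the xenobiotic-sensing receptor PXR, -0.49 ± 0.17. High diarrhoea 1 had the lowest enterocyte score (-1.61), and without it the camera adjusted p was 1.52e-07 and the median -0.468 for enterocyte genes. The enterocyte scores of the groups overlapped, with high diarrhoea 3 (0.2639) above low diarrhoea 2 (0.2498) (exact permutation p = 0.0571 with all libraries). Without high diarrhoea 3 the median of the xenobiotic list was -0.813. Tight junction and barrier genes did not pass (24 members, median -0.12, mean 0.15, camera adjusted p = 0.323), and their median lay between -0.212 without low diarrhoea 2 and -0.0175 without low diarrhoea 3.

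Goblet cell and mucus genes went both ways. Of 22 members 12 were lower and 10 higher, 5 and 3 of them past the threshold adjusted over the list alone, and camera placed the list lower (adjusted p = 0.0371; adjusted p = 0.679 with an estimated correlation) with a median log2 fold change of -0.14 and a mean of 0.21. The goblet cell trefoil peptide TFF3 had -1.38 ± 0.33 (SE) and the mucus protein FCGBP -1.48 ± 0.45. The 3 higher members were the gastric mucin MUC5AC (5.61 ± 1.42), TFF1 (3.81 ± 1.28) and the galectin LGALS15 (3.09 ± 0.97), and without high diarrhoea 1 MUC5AC had 3.31 and TFF1 1.09. MUC5AC and TFF1 are also on the Brunner gland and abomasum list. With members shared between lists left out, the goblet list ranked lower at the preset correlation (camera adjusted p = 0.00484). CLCA1, a secreted mucus-processing protein, measured 200.2 CPM ± 112 (SD, n = 4) in high and 607 CPM ± 272 (SD, n = 4) in low diarrhoea, and the gel-forming mucin MUC2 (LOC780488) had -0.75 ± 0.46. Without high diarrhoea 4 the goblet call ended (camera adjusted p = 0.956), as it did without high diarrhoea 3 (0.0911) or low diarrhoea 1 (0.0534). The median was -0.226, 0.0808, -0.257 and -0.0614 without high diarrhoea 2, high diarrhoea 4, low diarrhoea 2 and low diarrhoea 4, and MUC2 had -1.44 and -0.493 without high diarrhoea 2 and 4.

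Tuft cell genes, which mark the epithelial cells that sense worms, were lower in 13 of 16 members, 1 adjusted over the list alone, with a median log2 fold change of -0.45 (camera adjusted p = 0.000433; adjusted p = 0.371 with an estimated correlation). The leukotriene-forming enzyme ALOX5 had -0.82 ± 0.19 (SE), and it is also made by leukocytes. POU2F3, the transcription factor that defines tuft cells, had -0.26 ± 0.30 (-0.403 without high diarrhoea 1, -0.104 without low diarrhoea 4). Enteroendocrine genes were higher in 24 of 27 members, 0 adjusted over the list alone in edgeR (3 at an unadjusted p below 0.05, 0 called by DESeq2), with a median of 0.42 (camera adjusted p = 0.0132; adjusted p = 0.572 with an estimated correlation). The prohormone-processing enzyme CPE had 0.95 ± 0.33 and the transcription factor ISL1 2.05 ± 0.83. ISL1 rests on high diarrhoea 1, at 4.24 log2 CPM against 0.472 to 1.61 in the other high-diarrhoea and 0.361 to 1.1 in the low-diarrhoea libraries. Without high diarrhoea 1 the log2 fold change was 0.395 for ISL1 and 0.569 for CPE, the median was 0.263 and the enteroendocrine list no longer passed (camera adjusted p = 0.127), nor did it without high diarrhoea 3 (0.0666) or low diarrhoea 1 (0.0931).

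Eosinophil genes were lower in 5 of 6 tested members (16 listed), 3 adjusted over the list alone, with a median log2 fold change of -0.62 (camera adjusted p = 0.00475; adjusted p = 0.371 with an estimated correlation). With the smooth muscle covariate the eosinophil list was far from passing (camera adjusted p = 0.998). CCR3, the eotaxin receptor, measured 0.411 CPM ± 0.287 (SD, n = 4) in high and 1.88 CPM ± 0.937 (SD, n = 4) in low diarrhoea, and SIGLEC5 (LOC114117768) had -0.78 ± 0.29 (SE). The type 2 response list did not pass (16 members, 12 lower, median -0.12, camera adjusted p = 0.491), nor did mast cell and basophil genes (8 members, 6 lower, median -0.09, camera adjusted p = 0.421). Neither median had a stable sign, with -0.193 without low diarrhoea 2 and 0.0417 without low diarrhoea 4 for type 2, and -0.31 without high diarrhoea 4 and 0.0378 and 0.0548 without high diarrhoea 2 and low diarrhoea 3 for mast cells. IL4 had 6 reads in total in each group and IL5 13 in each, too few to test, and IL13 was listed at 0. The mast cell protease gene CPA3 had 33 reads in high and 73 in low diarrhoea, also too few to test, and EPX was not analysed here. The intelectin ITLN2 had -0.83 ± 0.58, and -1.38, -0.511 and -0.47 without high diarrhoea 3, high diarrhoea 4 and low diarrhoea 1. The anti-inflammatory cytokine IL10 had 0.08 ± 0.37, without a stable sign (-0.113, -0.128 and -0.0264 without high diarrhoea 2, low diarrhoea 1 and low diarrhoea 2, and 0.401 without low diarrhoea 3).

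Cell cycle genes were lower in 27 of 28 members, with a median log2 fold change of -0.36 (camera adjusted p = 6.6e-05; adjusted p = 0.572 with an estimated correlation), and the replication helicase genes MCM3 and MCM2 had -0.52 ± 0.25 (SE) and -0.56 ± 0.28. Endothelium and lymphatic genes were lower in 15 of 16 members, with a median of -0.33 (camera adjusted p = 0.0142; adjusted p = 0.572 with an estimated correlation), and the endothelial genes PLVAP and VWF had -0.73 ± 0.26 and -0.71 ± 0.25. Unfolded protein response genes were lower in 16 of 19 members, with a median of -0.17 (camera adjusted p = 0.022; adjusted p = 0.611 with an estimated correlation), and DNAJB9 and the stress sensor ERN1 had -0.27 ± 0.15 and -0.22 ± 0.13. In each of these 3 lists 0 members passed adjusted over the list alone in edgeR and 0 were called by DESeq2, with 0, 3 and 0 members at an unadjusted p below 0.05. Leaving out single libraries ended the endothelial call (high diarrhoea 3, 0.107; high diarrhoea 4, 0.0534; low diarrhoea 3, 0.204; low diarrhoea 4, 0.0794) and the unfolded protein call (high diarrhoea 4, 0.312; low diarrhoea 1, 0.0931; low diarrhoea 2, 0.075). The cell cycle median was -0.234, -0.674 and -0.219 without high diarrhoea 1, high diarrhoea 2 and low diarrhoea 1, and MCM3 had -0.347 without high diarrhoea 1. The endothelial median was -0.521, -0.187 and -0.19 without low diarrhoea 2, 3 and 4. The unfolded protein median was -0.333, -0.0851 and -0.0838 without high diarrhoea 2, high diarrhoea 4 and low diarrhoea 1, and DNAJB9 had -0.174 without high diarrhoea 4.

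The other lists did not pass in camera. The adjusted p was 0.0889 for complement (21 members, median log2 fold change -0.38), 0.0909 for Brunner gland and abomasum (8 members, median 4.62), 0.0922 for type I interferon response (21 members, median 0.37) and 0.141 for regulatory T cells and checkpoints (19 members, median -0.15). It was 0.184 for ion and water transport (29 members, median -0.02), 0.219 for dissection stress and immediate early genes (22 members, median 0.16) and 0.267 for neutrophils and acute inflammation (16 members, median -0.13, mean 0.06). It was 0.521 for crypt stem and Paneth cells (17 members, median -0.01, mean 0.09), 0.764 for Th17 and antimicrobial genes (13 members, median 0.07) and 0.846 for cholesterol and lipid synthesis (25 members, median 0.05). The medians of these lists all moved by over 1.5 times when single libraries were left out, and changed sign for type I interferon, ion and water transport, neutrophil, crypt, Th17 and cholesterol genes. Some of these lists came past the threshold when 1 library was left out. Brunner gland genes did so without high diarrhoea 4 (0.000101) or low diarrhoea 2 (0.0499), and also with the filter of CPM above 1 (0.0413), and their median was 2.06 without high diarrhoea 1. Type I interferon genes did so without high diarrhoea 1 (0.00949), 2 (0.0176) or 3 (0.0496), and also with the replicate block (0.022), but ranked lower without high diarrhoea 4 (0.47). Complement did so without high diarrhoea 2 (0.0259) or low diarrhoea 3 (0.0336) and with the block (0.0406), neutrophil genes without high diarrhoea 2 (0.0176), ion and water transport without high diarrhoea 1 (0.0342) and dissection stress without high diarrhoea 4 (0.0498). The pancreas and blood lists had 2 and 1 tested members and the sex-linked list 0, so they were not tested in camera. The chloride channel gene CFTR was listed at 0.

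The genes with the lowest unadjusted p did not pass over all genes tested, each with an adjusted p of 0.189 in edgeR. Among those lower, IDO2, a tryptophan-degrading enzyme, measured 1.75 CPM ± 0.225 (SD, n = 4) in high and 5.19 CPM ± 0.385 (SD, n = 4) in low diarrhoea (log2 fold change -1.57 ± 0.21, SE). TTI2, a chaperone cofactor of large signalling kinases, had -1.01 ± 0.16, HSD11B2, which inactivates cortisol, -1.34 ± 0.27 and the purine-salvage enzyme PNP -1.12 ± 0.24, with ITGAX as the fifth. Among those higher, the growth factor IGF1 measured 45.6 CPM ± 13.6 (SD, n = 4) in high and 19.9 CPM ± 1.23 (SD, n = 4) in low diarrhoea (1.20 ± 0.20). The neuronal transcription factor MYT1L had 2.24 ± 0.39, DUSP27 3.75 ± 0.69 and the sodium-calcium exchanger SLC8A1 1.58 ± 0.30. MYT1L rests on few reads, at 1.28 CPM in high and 0.265 CPM in low diarrhoea. Without high diarrhoea 1 the high-diarrhoea mean of DUSP27 was 8.36 CPM, against 15.8 CPM with it. All 9 had groups that did not overlap.

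The authors' deposited table calls 827 genes at an adjusted p below 0.05, 649 higher and 178 lower. In the authors' deposited table the adjusted p is 7.44e-08 for IDO2, 0.000271 for IGF1 and 0.0303 for MYH11. Of the genes in the authors' deposited table with such a call, 784 were tested in edgeR here and 767 were also called by DESeq2 here.

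**Figure D3:**
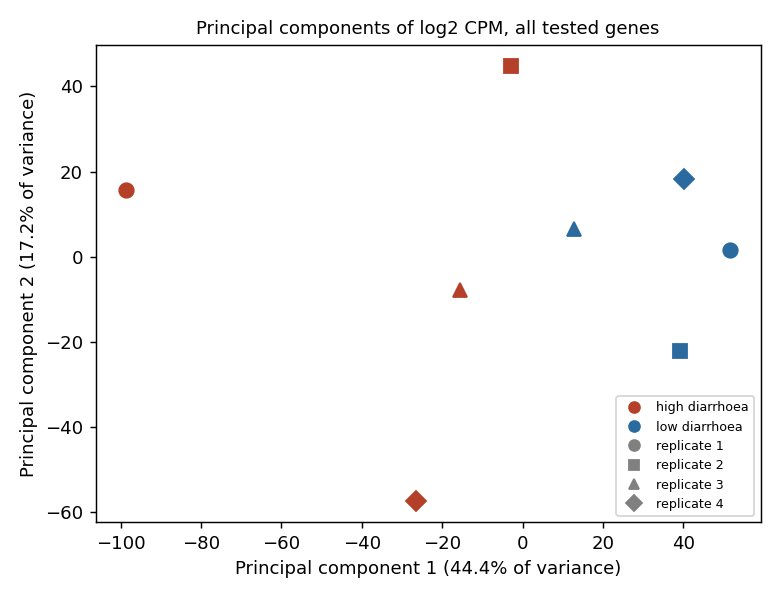
The 8 libraries on the first and second principal components of log2 CPM over all tested genes (axes in component units, with the percent of variance on each), coloured by group, with marker shapes for replicate numbers. High diarrhoea 1 lies farthest out on the first component at -98.7, and the low-diarrhoea libraries lie between 12.8 and 51.6.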

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

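A library is listed here when its gap to the nearest of the other 3 in its group, divided by the group's range, was above Dixon's 95% critical value for 4 samples. Of 210 such group tests 15 passed, and chance alone gives about 5%, so single entries carry little weight. The tests of high diarrhoea 1 alone, of the epithelial median alone, of the likelihood-ratio method and of library scaling were chosen only after the results were seen.

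High diarrhoea 2 had a mast cell and basophil score of -1.01 (others 0.156 to 0.175), a cell cycle score of 1.05 (others -1.03 to -0.754) and a complement score of 0.212 (others -0.335 to -0.245). Low diarrhoea 3 stood nearer to the high-diarrhoea libraries in 5 values, and lay within their range in each. These were its T cell score of 0.266 (others 0.678 to 0.751), plasma cell score of 0.328 (others 0.557 to 0.577), extracellular matrix score of 0.454 (others -0.977 to -0.883), Brunner gland score of -0.00837 (others -0.399 to -0.363) and log2 CPM of SPIB at 4.5 (others 5.11 to 5.23). Low diarrhoea 4 had a Th17 and antimicrobial score of 0.297 (others -0.183 to -0.122) and a log2 CPM of PNP of 6.49 (others 7.07 to 7.10). Low diarrhoea 1 had a log2 CPM of FCGBP of 11.3 (others 10.3 to 10.4). High diarrhoea 1 had a log2 CPM of TNFRSF13C of 0.976 (others 1.83 to 1.93) and of GZMA of 2.21 (others 3.42 to 3.62). High diarrhoea 4 had a log2 CPM of MX1 of 7.72 (others 4.96 to 5.39) and of LGALS15 of 3.92 (others 9.29 to 10.1).

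Muscle and matrix lists ranked higher and immune lists lower in high diarrhoea, and a piece of duodenum with more muscle wall is a candidate explanation. If muscle diluted the mucosa evenly, immune and epithelial genes would fall together, and the enterocyte genes were lower with the immune lists (31 of 33, median log2 fold change -0.73), but the median log2 CPM of 23 epithelial junction genes was 5.95 ± 0.2 (SD, n = 4) in high and 5.93 ± 0.141 (SD, n = 4) in low diarrhoea (difference 0.0274, exact permutation p = 0.771), so the epithelial lists give no single answer. Within libraries, the median of 87 immune genes minus this one was -2.68 ± 0.682 (SD, n = 4) in high and -1.74 ± 0.268 (SD, n = 4) in low diarrhoea, a difference of -0.939 (exact permutation p = 0.0571), which is on the side of 0.05 set beforehand for even dilution, and although a missed threshold does not show equality, this spread keeps it open, so even dilution and a lower immune share cannot be told apart with 4 libraries per group. Without high diarrhoea 1 all 13 smooth muscle genes were still higher, with a median log2 fold change of 1.77 against 2.29 (camera adjusted p = 8.2e-09). The other high-diarrhoea libraries scored 0.0979 to 0.827, above every low-diarrhoea library (-1.36 to -0.122). For smooth muscle these values argue against a difference carried by that library alone. Without it, however, the list did not pass with an estimated correlation (adjusted p = 0.32) and its scores missed the threshold (exact permutation p = 0.0857). A difference shared by the group is therefore not established. For matrix genes a difference carried by that library alone stays open, since low diarrhoea 3 (0.454) scored above the other high-diarrhoea libraries (0.202 to 0.419). Chance cannot be excluded either, since 5 of the 35 splits of the 8 libraries gave at least as many lists as the real 20 (highest other split 23, lowest 4). A difference between the diarrhoea groups themselves stays open.

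DESeq2 called 798 genes where the quasi-likelihood test called 0 (2645 at an unadjusted p below 0.05). Library scaling did not account for it, because the quasi-likelihood test with size factors of the DESeq2 kind also called 0. The edgeR likelihood-ratio test on the same dispersions, which takes each gene's estimated spread as exact, called 639, so the handling of uncertainty in the spread may account for much of the gap. Because the real split gave 0 genes in the quasi-likelihood test, all 35 splits of the libraries give at least as many (highest other 2), which says nothing about chance, but 3 gave at least its 2645 genes at an unadjusted p below 0.05 (highest other 3546) and 3 gave at least its 798 DESeq2 calls (highest other 1402), so chance was not excluded for these 2 counts. The split with 1402 exchanged high diarrhoea 2 for low diarrhoea 4.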

How the results depend on the processing

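The comparisons with a smooth muscle covariate, the likelihood-ratio test, DESeq2 on all genes, DESeq2 without high diarrhoea 1, lists without shared members and camera with an estimated correlation without high diarrhoea 1 were chosen after seeing the data. The count of genes was 0 in edgeR (2645 at an unadjusted p below 0.05), and also 0 with voom, both with and without quality weights, limma on the authors' values, other scaling factors, other filters, the robust fit and the looser or stricter thresholds. It was 798 with DESeq2, 831 with DESeq2 on all genes, 259 with DESeq2 without high diarrhoea 1 (228 shared with the 798) and 639 with the likelihood-ratio test. Leaving out each library gave 0 to 1, the 1 being LOC114109558 without high diarrhoea 2, where its 3 remaining high-diarrhoea libraries had 525, 2920 and 3309 reads and the low-diarrhoea libraries 0, 0, 3 and 1. The count of lists was 20, and 0 with an estimated correlation (camera), 0 likewise without high diarrhoea 1 (5 at an unadjusted p below 0.05), 0 with fry, 0 with the exact permutation of scores (6 at an unadjusted p below 0.05) and 5 with the smooth muscle covariate. At the preset correlation it was also 20 for lists without shared members. Leaving out each library gave 17 to 23 lists, and 15 lists passed in all 8 of these fits. The covariate follows the groups closely, and with it 0 genes passed (358 at an unadjusted p below 0.05) and of the 20 lists that had passed 3 changed direction, namely plasma cell (adjusted p = 0.982), enteroendocrine (0.475) and enteric neuron and glia (0.00108), as did 6 of the 13 that had not passed. The macrophage and dendritic cell (6.6e-06), tuft cell (0.00256), cytotoxic (0.0101) and mitochondrial (0.00014) lists still passed. With the covariate the log2 fold change changed sign for TFF1 (-0.58), S100B (-0.21), IFNG (0.33), ERN1 (0.12), IL10 (-0.00687), ISL1 (-0.42) and CPE (-0.033). Leaving out libraries took IL10 to between -0.13 and 0.40. The cause was not tested. The filter of CPM above 1 ended the goblet call (adjusted p = 0.112). The replicate numbers shared by the groups are not said to pair the samples. Same-numbered libraries deviated with correlations of -0.176, -0.0978, -0.0916 and -0.0831. In these deviations no high-diarrhoea library correlated best with its own number. These values give no sign of pairing but cannot exclude it. With the numbers as a replicate block 0 genes passed (2100 at an unadjusted p below 0.05) and 22 lists. Genes near 1 CPM, such as CCR3, IFNG, POU2F3, MYT1L and SLC2A2, rest on few reads and are limited by depth.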

Other observations

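The test of overlapping gene spans was chosen only after the result was seen, and so were the genes named in this part. None of these genes passed over all genes tested in edgeR.

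Genes typical of gastric surface and Brunner gland epithelium were high in some of the high-diarrhoea libraries. Of the 8 tested members of that list, 6 were higher and 1 lower past the threshold adjusted over the list alone. MUC5AC (LOC101105731), the gastric surface mucin, measured 37.5 CPM ± 60.5 (SD, n = 4) in high and 0.757 CPM ± 0.509 (SD, n = 4) in low diarrhoea. Its log2 CPM was 6.999, 3.97 and 2.61 in high diarrhoea 1, 2 and 3, against -0.24 in high diarrhoea 4 and -1.48 to 0.59 in low diarrhoea. The trefoil peptides TFF1 and TFF2, the gastric protein GKN1 and the gland water channel AQP5 were likewise highest in high diarrhoea 1, at 10.1, 12.6, 6.63 and 6.997 log2 CPM. The same library had the highest smooth muscle score. Without it the log2 fold change was 3.31 for MUC5AC, 1.09 for TFF1, 2.75 for TFF2, 4.32 for GKN1 and 3.33 for AQP5, and the mean of MUC5AC in high diarrhoea was 7.46 CPM. AQP5 had 8.45 without low diarrhoea 3.

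Of the Th17 and antimicrobial list 3 members were higher and 1 lower adjusted over the list alone. The epithelial oxidase DUOX2 measured 5.90 CPM ± 4.43 (SD, n = 4) in high and 0.852 CPM ± 0.629 (SD, n = 4) in low diarrhoea, its maturation factor DUOXA2 had a log2 fold change of 4.5 ± 1.14 (SE), and the iron-binding protein LTF 5.58 ± 1.81. The groups overlapped for DUOX2, with high diarrhoea 4 (0.637 log2 CPM) below low diarrhoea 4 (0.648). For DUOXA2, high diarrhoea 4 (-0.818) lay below low diarrhoea 3 and 4 (-0.496 and -0.359). Without high diarrhoea 2 the high-diarrhoea mean of DUOXA2 was 3.41 CPM, against 8.97 CPM with it. LTF rests on high diarrhoea 1 and 2, at 11.3 and 8.87 log2 CPM, with high diarrhoea 4 (1.82) below all low-diarrhoea libraries (2.18 to 5.46), and without high diarrhoea 1 it had 3.43. TFF2 of the Brunner gland list was also highest in high diarrhoea 1 (12.55), then high diarrhoea 2 (10.55), then low diarrhoea 3 (7.94), as LTF was. Because of this shared order, LTF was not taken as separate evidence of an antimicrobial response. The cause of the shared order was not tested. LYZ, a lysozyme gene that may share reads with copies, had -1.56 ± 0.37, and its log2 fold change lay between -1.82 and -0.59 over the 16 settings computed. The prostaglandin synthase PTGS2 had 2.91 ± 0.74, and its range over the settings was 0.17 to 3.62, lowest with the smooth muscle covariate and 1.91 without high diarrhoea 1. LGALS15, a galectin studied in sheep with worm infections, measured 613 CPM ± 444 (SD, n = 4) in high and 72.0 CPM ± 52.1 (SD, n = 4) in low diarrhoea, with high diarrhoea 4 below all low-diarrhoea libraries and a low-diarrhoea mean of 46.3 CPM without low diarrhoea 4. ITLN2_1, a second copy of the intelectin gene whose reads may be split with ITLN2, had -2.15 ± 0.53. The hormone GUCA2A, which regulates intestinal fluid secretion, had -1.61 ± 0.51. The interferon-induced genes MX1 and MX2 were highest in high diarrhoea 4, at 7.72 and 6.91 log2 CPM, and without it the log2 fold change was 0.119 and 0.612.

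Some genes that a duodenum uses, among them JCHAIN, CNN1, AIF1 and HAX1, were listed at 0 in all 8 libraries. If reads in overlapping gene spans were left out of the counts, as may be the case, genes inside others would be at 0 more often. Of 509 protein-coding genes lying inside the span of another gene in the RefSeq table, 228 (44.8%) were at 0, against 8.02% for length-matched genes that overlap none, a ratio of 5.59. This fits JCHAIN, which lies inside another gene, but CNN1 and HAX1 overlap none in that assembly, and the authors' build is not known. No biological explanation was tested, and a gene at 0 here is no evidence that it was off.

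LOC114112617 and LOC114115287, among the most abundant identifiers, have no name in the RefSeq table. The second took 4.05% ± 0.557 (SD, n = 4) of reads in high and 2.42% ± 0.354 (SD, n = 4) in low diarrhoea (exact permutation p = 0.0286, adjusted p = 0.0952 over the 10 library measures).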
